A study of Gulosibacter molinativorax with 2 samples.

How the data were processed

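RNA sequencing of a bacterium was compared between 2 growth media, with 1 library per medium. Strain ON4T is the type strain of Gulosibacter molinativorax, an actinobacterium known for breaking down molinate, a thiocarbamate herbicide used in rice fields. One library came from cells grown in a mineral medium supplemented with molinate and the other from cells grown in LB, a rich broth of digested protein and yeast extract. Per the labels' protocols, exponentially growing cells were pelleted and stabilised, total RNA was extracted with a column kit, mRNA was enriched by subtractive hybridization, and whole-transcriptome libraries were made with an Ion Torrent kit. The study's design text also mentions RT-qPCR, which was not analysed here.

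Each library was deposited as a table of 3244 targets, and both tables list the same targets with the same lengths. Per the file headers, the authors deposited for each target a total read count, a count of reads unique to that target, and an estimated count. In the values, a read that maps to several targets enters the total count of each and is divided between them in the estimated count, which was not whole for 93 targets in the molinate table and for 97 in the LB table, and lay between the unique and the total count for every target. The deposited FPKM values, taken with the deposited effective lengths, gave back library totals of 410279 and 282915 estimated reads. They did so within 1% for 99.9% of targets with reads in the molinate table and 100.0% in the LB table. The deposited TPM values have the same sum in both libraries. The column names are those that the eXpress quantifier writes; the aligner, the quantifier's version, the genome build and whether strand was used are not given in the sources used here.

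The tables pair the target identifiers with no gene names, products or positions, and no reference table or genome was used. Gene lists fixed in advance by product name could therefore not be matched. Molinate hydrolase was not analysed here as a named gene, and ribosomal RNA genes were not set apart. By the rule set for that case, at most 2 identifiers are printed per direction. They are the highest ranked by the interval bound nearest to 0, among targets with a summed estimated count of at least 50, with targets that share all reads counted as 1. The rule also took the 10 targets with highest TPM per library and the 5 longest runs per direction with ties included, which gave all 6 lower runs; these are described without identifiers. Of the 3244 lengths, 3240 were multiples of 3, as of coding sequences without untranslated regions. Identifiers carry a number, and 3236 of them run without leading zeros up to 3293. Whether these numbers follow the order of genes on the genome is not stated in the sources used here, so positions are described as identifier numbers only.

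With 1 library per medium there is no replicate, and no test between the conditions was made; ratios, intervals and counts of targets describe these 2 libraries. The estimated counts were rounded. The log2 ratio of molinate over LB was computed with a prior count of 0.5 added to each library, after scaling by edgeR's TMM factors (0.776 for the molinate library and 1.29 for the LB library) from targets with a summed count of at least 20. Each ratio has a 95% exact (Clopper-Pearson) conditional binomial interval, which covers counting error only. It treats reads as independent molecules, which reads without molecular identifiers need not be, so it may be too narrow. Printed folds are ratios of reads without the prior count. A target was counted as higher or lower when its ratio with the prior count was at least 2-fold and its interval excluded equality. Where a library had 0 reads, a bound was computed from a floor of 3 reads in it. This floor gives a larger fold than the end of the 2-sided exact interval, so both are printed. A target was counted as having 0 reads when its total count, shared reads included, was 0. The distance from the middle to the end of the log2 interval had a median of 1.18 for the 567 targets with 20 to 50 reads in both libraries together, 0.65 for the 918 with 50 to 200 reads, and 0.32 for the 655 with more. Targets were joined into families where the tables put them in 1 group with shared reads in either library.

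The alternatives fixed before the data were examined were DESeq2 size factors, scaling by total, uniquely mapped counts, deposited TPM ratios, other count minimums, another prior count and stricter call rules. Alternatives added after seeing the data were families as 1 unit, leaving out the last stretch of identifier numbers, leaving out the 3-copy family, and other settings for runs of consecutive numbers. Runs took the place of a planned search of neighbouring genes that needed positions. The rule was tested on simulated data: Poisson counts of 3244 targets, drawn from the means and totals of these libraries, held 200 changed targets, chosen among those expected to pass the count minimum. All 100 targets changed 4-fold and all 100 changed 8-fold were called, and 17 of 1980 unchanged targets were called. The simulation holds counting noise only, not the spread between cultures. Both simulated libraries were drawn from 1 common composition, with as many changes up as down. It therefore did not test the scaling of libraries in which 1 family takes 24.3% of the reads of only 1 of them. Python 3.11.15, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.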

Results

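The transcriptome of strain ON4T was measured during growth in mineral medium with molinate and during growth in LB, with 1 library for each medium, to describe how expression differs between growth with and without the herbicide. The 2 media differ in more than molinate, so each difference is one between whole media. The molinate library held 410279 estimated reads on 3244 targets and the LB library held 282915. In the molinate library 359 targets (11.1% of those listed) had no read, in the LB library 287 had none, and 145 had none in either. Reads that mapped to more than 1 target made up 25.0% of the molinate library and 0.52% of the LB library. The tables give no gene names, so targets are described by length, by identifier number and by the reads they share.

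One family of 3 targets dominated the molinate library and was almost without reads in LB. Its 3 members, among them GMOLON4_3280, are each 1398 bases long, and no read of either library was unique to 1 of them. Together they took 99549 reads in molinate medium, which was 24.3% of the library (95% exact interval 24.1 to 24.4%). In LB they took 3 reads, or 0.0011% (95% exact interval 0.00022 to 0.0031%). After TMM scaling the family was 37979-fold higher in molinate medium, with a 95% exact counting interval from 12996-fold to 184169-fold. The quantifier divided the reads evenly, with 33183 estimated reads per copy in molinate medium and 1 per copy in LB, so which copy was transcribed cannot be read from these values. There was no replicate of either medium, and the interval covers counting error only.

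**Figure D1:**
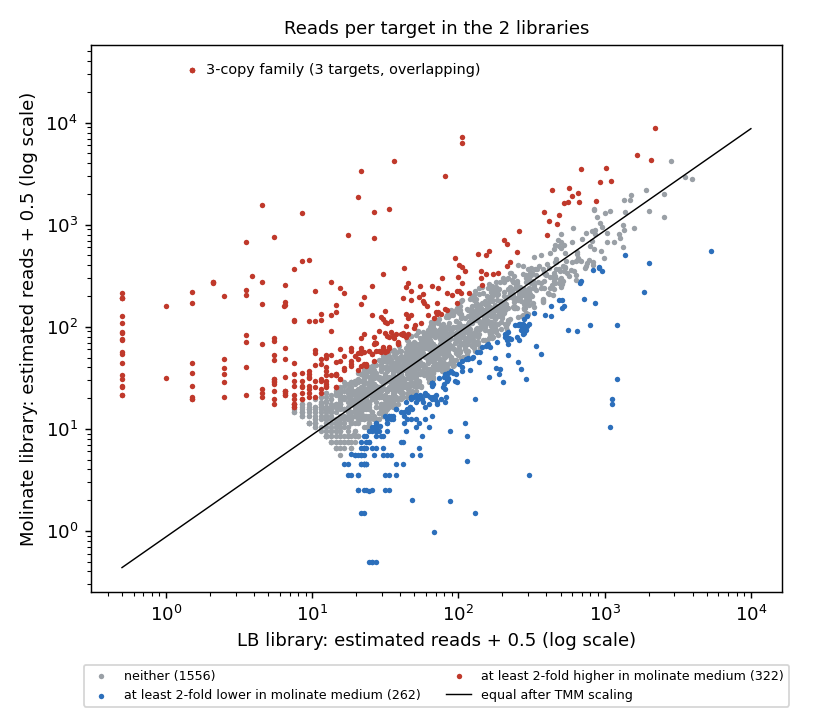
Estimated reads per target (plus 0.5) in the LB library on the x axis and in the molinate library on the y axis, both on log scales, for the 2140 targets with at least 20 reads in both libraries together. Red points (322) were at least 2-fold higher and blue points (262) at least 2-fold lower in molinate medium, the line marks equality after scaling, and the 3 overlapping points of the 3-copy family stand at 33183 estimated reads, above every other target.

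The libraries differed at many targets in both directions, and ratios of at least 32-fold, prior count included, were more often toward molinate medium. Of 2140 targets with at least 20 reads in both libraries together, 322 (15.0%) were at least 2-fold higher in molinate medium and 262 (12.2%) at least 2-fold lower. The other 1556 stayed within 2-fold or had an interval that included equality. At 4-fold the counts were 153 higher and 80 lower, and at 32-fold they were 54 higher and 12 lower. These thresholds apply to the ratio with the prior count, so targets at 0 reads in 1 library pass 32-fold even where their interval reaches far below it. The 54 include 15 targets with no LB read and a further 6 whose estimated LB count rounds to 0. The 12 include 2 with no molinate read and a further 3 whose estimated molinate count rounds to 0. The 3 targets of the family are among the higher ones; without them 319 of 2137 targets were higher at 2-fold, 150 at 4-fold and 51 at 32-fold. The 322 higher targets took 53.4% of the molinate reads and 9.23% of the LB reads. Without the 3-copy family, the higher targets still took 29.1% of the molinate reads. The 262 lower targets took 17.3% of the LB reads and 2.90% of the molinate reads. Across the 2140 targets, log2 values of the 2 libraries correlated with Pearson r = 0.607 and Spearman rho = 0.716, and without the family Pearson r was 0.641. Pearson r also depended on the count minimum, at 0.319 with a summed count of at least 100 and 0.776 with no minimum above 0. These are across targets, which are not independent replicates.

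The balance of higher against lower targets depended on the scaling. With TMM scaling the median log2 ratio was 0.02 and 55.1% of the calls were higher. Scaling by total estimated reads moved the median to -0.71, with 183 targets higher and 759 lower, so that 19.4% of the calls were higher. With the deposited TPM values, 242 were higher and 481 lower (33.5% higher), at a median of -0.36. All further ratios are TMM-scaled and so are relative to the typical target.

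Targets with consecutive identifier numbers often differed in the same direction. There were 20 runs of at least 4 consecutive numbers that were all higher or all lower, holding 130 targets. Shuffling the targets over the numbers 1000 times gave at most 4 runs and a longest run of 6. Of the 20 runs, 14 were higher in molinate medium, with 96 targets, and 6 were lower, with 34 targets. The fold of a run pools the reads of its members, so its interval does not describe their spread. Every member had to be called in the same direction, so a pooled difference in that direction was bound to follow. The number of runs was 51 with total scaling and 12 at a 4-fold threshold.

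Among the 5 longest higher runs, a run of 12 targets was both abundant and far apart between the media. It took 27640 molinate reads, 6.74% of that library, and 390 LB reads, and was 81.1-fold higher (95% exact counting interval 73.4 to 89.9). Its members ranged from a log2 ratio of 3.97 to 7.63. The longest run, of 15 targets, took 3335 molinate and 77 LB reads and was 49.6-fold higher (39.5 to 63.0), with members from 3.48 to 8.19. Its member with fewest LB reads had 0, so the upper end of this range may rest on the prior count as well. A run of 7 targets was 46.2-fold higher (38.5 to 56.0) on 4725 molinate and 117 LB reads, with members from 3.46 to 6.06. A run of 13 targets was abundant in both media, with 29616 molinate and 8568 LB reads, and was 3.96-fold higher in molinate medium (3.86 to 4.05). Its members ranged from a log2 ratio of 1.27 to 2.55. This run held the target with most molinate reads outside the 3-copy family, 1482 bases long, with 8908 molinate reads against 2219 in LB and a log2 ratio of 2.20 (2.13 to 2.27). A run of 8 targets near the end of the numbering had 434 molinate reads and 2 LB reads and was 248-fold higher (68.3 to 2057). It lies within the last 40 identifier numbers described below, as does a higher run of 4 targets, so these runs are not separate from that stretch.

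Among the 6 lower runs, the largest difference was in 4 consecutive targets that included GMOLON4_2716 and GMOLON4_2717. This run took 4546 LB reads and 76 molinate reads and was 52.3-fold higher in LB (95% exact counting interval 41.7 to 66.5). The longest lower run, of 10 targets, took 6606 LB reads, 2.33% of that library, against 915 molinate reads, and was 6.31-fold higher in LB (5.89 to 6.77). Its members lay between log2 ratios of -3.35 and -1.49. A run of 8 targets had 376 LB reads and 28 molinate reads and was 11.7-fold higher in LB (7.99 to 17.9). The other lower runs, each of 4 targets, had log2 ratios of -3.62 (-4.56 to -2.88), -2.06 (-2.59 to -1.59) and -1.42 (-1.56 to -1.28). The first of them had 203 LB reads and 14 molinate reads. The target with most LB reads lay in no run. It is 1650 bases long and had 5366 LB and 554 molinate reads, a log2 ratio of -3.08 (-3.21 to -2.95).

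**Figure D2:**
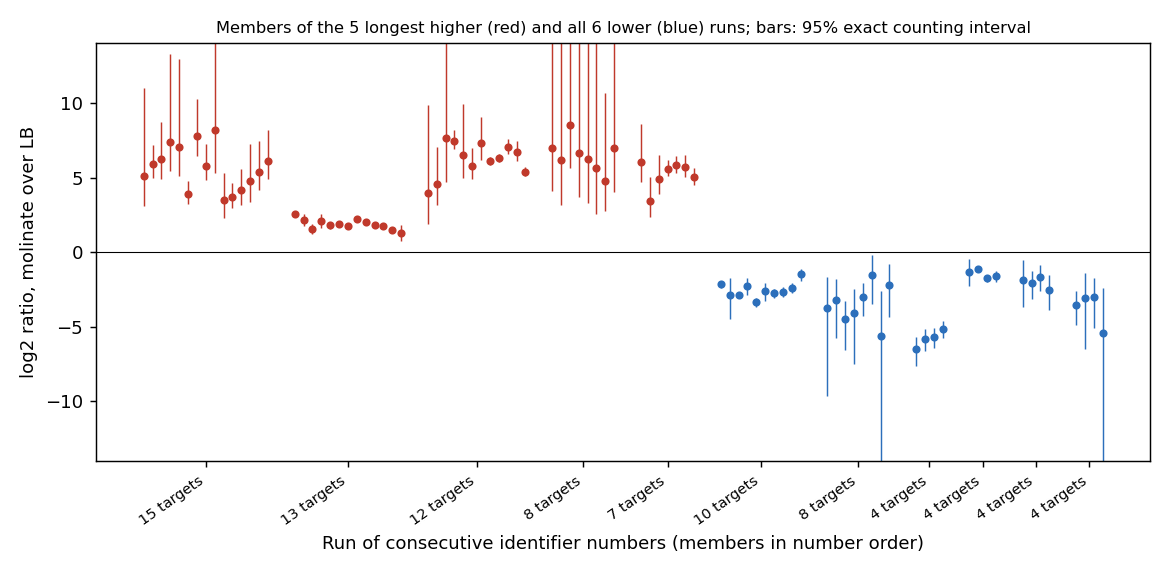
Log2 ratio of molinate over LB (y axis) for each member of the 5 longest higher runs (red) and all 6 lower runs (blue) of consecutive identifier numbers, in number order along the x axis. Bars are 95% exact counting intervals, drawn only to the axis limits where they extend further. The members of the 12-target run lie between 3.97 and 7.63, the latter resting on the prior count for a target with no LB read. Those of the 10-target run lie between -3.35 and -1.49.

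The last 40 identifier numbers were nearly silent in LB. Each of these targets had at most 3 LB reads, and together they had 6 LB reads against 100621 molinate reads. The 3-copy family lies among them. The other 37 targets had 1072 molinate reads and 3 LB reads, a 409-fold difference (95% exact counting interval 140 to 1986). Of these 37, 28 had molinate reads, 9 had no read in either library, and 16 passed the count minimum. In the 3157 other, overlapping windows of 40 targets, LB reads had a median of 2862 and a minimum of 36.4. The limits of the stretch were set after its values were seen, by the low LB reads themselves, so any of its targets that passed the count minimum was bound to be higher in molinate medium.

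**Figure D3:**
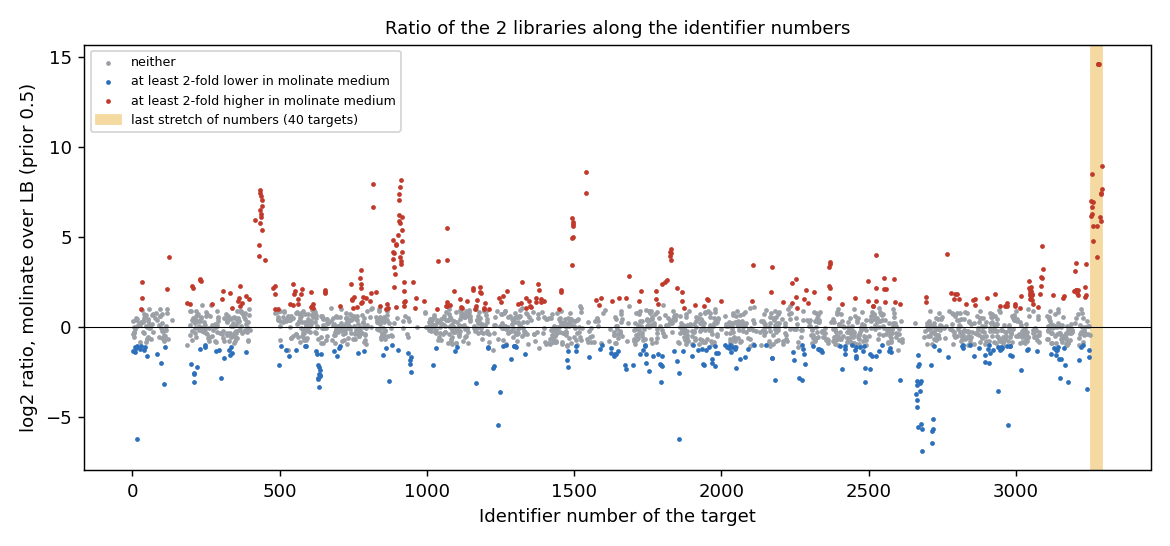
Log2 ratio of molinate over LB (y axis, prior count 0.5) against the identifier number of each target past the count minimum (x axis). Red points were at least 2-fold higher and blue points at least 2-fold lower in molinate medium; the shaded last stretch of 40 numbers, chosen for at most 3 LB reads per target, holds 19 targets past the minimum.

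Single targets outside the families ranked next. GMOLON4_1539, 1062 bases long, had 1569 molinate reads and 4 LB reads, a log2 ratio of 8.64 (95% exact counting interval 7.45 to 10.69). In the other direction, GMOLON4_2716, 1185 bases long, had 1080 LB reads and 10 molinate reads, a log2 ratio of -6.49 (-7.62 to -5.68). GMOLON4_2717, 1035 bases long, had 1123 LB reads and 17 molinate reads, a log2 ratio of -5.81 (-6.64 to -5.17). With at least 20 molinate reads and no LB read mapped, shared reads included, there were 15 targets. A further 6 had shared LB reads only, with an estimated count that rounds to 0. Of the 15, 12 lie in the last 40 identifier numbers, a stretch set by its low LB reads. Among other targets with plain numbers and at least 20 molinate reads, 3 of 1641 had no LB read. The one of the 15 with most reads (215) lies in the last stretch. It was at least 82.0-fold higher, taking 3 reads in the LB library as the floor, and the lower end of its 95% exact interval was 66.1-fold. With at least 20 LB reads and no molinate read mapped there were 2 targets, and a further 3 had shared molinate reads only, with an estimated count that rounds to 0. Of the 2, the one with most reads (25) was at least 7.28-fold lower on a floor of 3 molinate reads, and the end of its 95% exact interval nearest to equality was 5.50-fold.

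Families of targets that share most of their reads differed in both directions. With at least 20 reads and more than 50% of reads shared there were 22 families, which hold 88 targets; 4 were at least 2-fold higher in molinate medium and 9 at least 2-fold lower. These 9 are not separate from the runs: 5 of them are pairs from 1 set of 17 pairs whose members lie about 2498 numbers apart. The same set holds 7 members of the lower run of 8 targets and 3 members of a lower run of 4 targets. Beside the 3-copy family, a family of 10 targets had 1966 molinate and 14 LB reads and was 161-fold higher (95.6 to 295). It holds the 8 targets whose identifier numbers are padded with zeros, 4 of which have lengths that are not multiples of 3. A family of 6 targets of 1215 bases was 2.98-fold higher (2.48 to 3.61) on 412 molinate and 158 LB reads. A family of 7 targets of 1149 bases had 94 LB reads and 2 molinate reads, a log2 ratio of -5.05 (-8.43 to -3.47). How the reads of a family divide among its members is uncertain.

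By deposited TPM, the 10 highest targets of each library had 3 targets in common. All 10 of the LB library were shorter than 500 bases, against 3 in the molinate library. The highest single target in both was one of 204 bases, at 103177 TPM in molinate medium and 101899 TPM in LB, on 2212 and 1922 reads. TPM divides reads by effective length, which the tables give as 33.2 bases for this target. In molinate medium the 3-copy family had 128851 TPM in sum, more than that target, and 42950 TPM per copy as its shared reads were divided.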

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

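Families as 1 unit, leaving out the last stretch of numbers, leaving out the 3-copy family and other settings for runs were tests chosen after the result was seen. The counts of higher and lower targets (322 and 262) were 322 and 262 with DESeq2 size factors, the same targets in each case. One or both moved by over 1.5 times with scaling by total (183 and 759), with deposited TPM (242 and 481), with a summed count of at least 100 (164 and 109), with an interval bound of at least 2-fold (192 and 89) and with a 4-fold ratio (153 and 80). All 262 lower targets remained lower under both scalings that gave more lower targets. This was bound to follow, as each of these scalings moves every log2 ratio and interval down by the same amount. The minimum of 100 left 1075 targets that could be called, against 2140, so its counts are out of fewer targets. Both stayed within 1.5 times with uniquely mapped counts (304 and 246), no minimum above 0 (396 and 330), a prior count of 5 (303 and 210), families as 1 unit (302 and 252), the last stretch of numbers left out (304 and 260) and the 3-copy family left out with the scale kept (319 and 262). The correlation of 0.607 became 0.672 with uniquely mapped counts, 0.776 with no minimum above 0, 0.319 with a summed count of at least 100, 0.677 with a prior count of 5, 0.661 with families as 1 unit, 0.670 without the last stretch and 0.641 without the 3-copy family; the cause of each move was not tested. The 4 named identifiers kept their direction under every alternative that could give a value. They were picked for extreme ratios, which these alternatives could hardly reverse, so this is no sign of robustness. On the log2 scale GMOLON4_3280 lay between 12.63 and 14.99, the latter for its family as 1 unit. GMOLON4_1539 lay between 7.65 and 8.64, GMOLON4_2716 between -7.22 and -5.98, and GMOLON4_2717 between -6.54 and -5.49. GMOLON4_3280 has no uniquely mapped reads and lies in the last stretch and in the 3-copy family, so it has no value under those alternatives. The planned gene list medians were not run because no names were paired with the identifiers. No paired analysis was possible because each medium has 1 library. Leaving out a library was not possible either, and the spread between cultures is unknown.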

Other observations

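Tests in this part were chosen after the result was seen, except those of shared reads, of target length and of the spread of LB reads within the last stretch, whose outcomes had not been seen when they were written down. Some targets came in pairs at a nearly constant distance in identifier numbers. Among 41 pairs of targets that share reads only with each other and are not neighbours, 17 lie within 5 numbers of the median distance of 2498, and 13 of these 17 have equal lengths. Together the 17 pairs had 724 LB reads and 89 molinate reads, a 7.11-fold difference toward LB (95% exact counting interval 5.70 to 8.96). The 2 copies did not carry the same number of reads in LB: of the reads unique to 1 copy, 387 fell on the copy with the higher numbers and 16 on the other. In sum 96.0% (95% exact interval 93.6 to 97.7%) were on 1 copy. This interval pools the reads of all 17 pairs, and 100 of the 387 fell on 1 target, so it does not describe how alike the pairs were. In molinate medium the unique reads numbered 33 and 25. The 12-target and 13-target runs that were higher in molinate medium are joined by 2 pairs whose members lie 2614 numbers apart, with unequal lengths and few shared reads. One pair has lengths of 1239 and 1206 bases, and 12 of its 11168 molinate reads map to both members. The other has lengths of 459 and 474 bases, and 3 of its 1103 molinate reads do so.

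The last 40 identifier numbers had almost no LB reads. Lower depth in LB is argued against: at the typical ratio of the libraries the 37 targets outside the 3-copy family would have had 1227 LB reads, against 3 observed and at most 111 that the limit of 3 LB reads per target would allow. Carry-over from the molinate library at the rate that the 3-copy family allows would give at most 0.094 of the 3 LB reads outside the family (exact Poisson probability 0.000131, 1-sided), and the odds of an LB read were 92.8 times higher outside the family than inside it (Fisher's exact test on the reads of these 2 libraries, 95% interval 12.4 to 694). Both values rest on 3 LB reads outside and 3 inside, cover counting error only and treat reads as independent molecules, so they exclude neither carry-over nor one common reduction of the stretch, as fewer copies of its DNA would give. Carry-over would add LB reads, so it bears only on the few that remain and not on their scarcity. Whether it gave those few cannot be told. For the scarcity, a reduction of the stretch and regulation by the medium cannot be told apart. LB reads are too few, and DNA was not analysed here. The spread of LB reads over the 37 targets gave an exact probability of 0.183, the smallest that test could give.

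Neighbouring identifier numbers differed alike, with a correlation of log2 ratios of 0.728 over 1709 pairs of consecutive numbers, and of 0.454 on ranks. The highest value in 1000 shuffled orders was 0.081, which argues against chance order. Reads shared between neighbours are argued against as well, since the correlation was 0.670 over 1599 pairs whose reads were all unique. Similar lengths could explain little of it, as ratio and length were barely related across targets (Spearman rho = 0.069). Removing a trend with length could therefore change little, and it left a correlation of 0.722. The correlation of log2 ratios declined to 0.397 at a distance of 5 numbers and 0.198 at 20. Among the 1028 pairs in which neither target was called it was 0.225. A hypothesis that may explain this is that the numbers follow the genome and that neighbours are transcribed together; without positions it was not tested.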
